A study of Canis lupus familiaris with 13 samples.

How the data were processed

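RNA was extracted from biopsies of the biceps femoris muscle of 4 dogs, taken under local anaesthesia and flash frozen, and 13 libraries were made with a SMART-Seq kit that copies full-length transcripts and with Nextera XT tagging, then sequenced on a NovaSeq instrument. The deposited table held 30951 genes with Ensembl identifiers, of which 17994 carried a symbol, and 5744 had 0 counts in all libraries. Its first kind of column held raw read counts, deposited by the authors as whole numbers per gene and library. Its second kind of column held a normalized signal, which the authors made by dividing each raw count by 1 size factor per library. These size factors were checked against the median of ratios over genes counted in every library and were equal to it. The normalized signal served only as a check on the columns, and the comparisons used the counts. The processing notes of the submitters name Bowtie 0.12.2 and the CanFam3.1 genome without saying how each was used. The program that counted reads, the annotation release and any strand setting were not given in the sources used here. The library kit does not mark the strand, so counts of a gene may include reads of a transcript on the other strand or of an overlapping gene. No coordinates came with the counts, and positions are not given here.

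Libraries were grouped by dog, by the stimulation in the labels (basal or insulin) and by a sample number from 0 to 3 whose meaning the labels do not state. Basal libraries carried sample number 0 and insulin libraries carried 1, 2 or 3. Dog 1 had no basal library. In insulin against basal it entered only the estimate of spread, and in the models of sample number its differences among samples 1 to 3 also entered the fold changes. The dog was a block in every model. To check that the dog numbers pair the libraries, deviations from the group means were correlated between libraries of different groups. The median r was 0.17 over 15 pairs of the same dog and -0.066 over 47 pairs of different dogs, and 12 of 13 libraries had their highest r with a library of their own dog. Deviations within a group cancel out, so r between different dogs tends to be negative where r within dogs is positive. The libraries of sample 3 mirror each other exactly, and the pairs are not independent. Between libraries of 1 group or 1 dog, chi-square per gene ranged from 47.2 to 726, so the spread was far above counting error and was estimated from the replicates.

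Counts were analysed in R 4.3.3 with edgeR 4.0.16, using the filterByExpr filter, TMM scaling and robust quasi-likelihood fits, which left 14629 genes. The insulin against basal model held dog and stimulation, and the other models held dog and sample number. The libraries of 1 dog under insulin were treated as independent given the dog, and a fit on counts summed per dog and stimulation was run as an alternative. P values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were obtained from the fold change and its F statistic. Expression levels (CPM) are counts scaled to the TMM adjusted library total and are given as the mean and standard deviation (SD) over libraries, dog 1 included. The models, gene lists, rule for naming genes and most alternatives were fixed before the data were examined.

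The rule named the 10 genes with the largest rise and the 10 with the largest fall past the threshold in insulin against basal. Each needed a mean log2 CPM of at least 1, a symbol and 1 direction in dogs 2, 3 and 4. For each comparison between sample numbers the rule took 5 and 5, or, where no gene passed, the 5 genes of lowest p with that mean and a symbol. It added up to 4 members of lowest p from each list, and 12 genes named whatever their result: PDK4, HK2, TXNIP, IRS2, FBXO32, TRIM63, SREBF1, SLC2A4, PPARGC1A, UCP3, FOXO1 and INSR. The values of 1 gene that the rule took are not reported here.

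The 34 gene lists held 676 symbols, of which 587 were found in the table. Lists on metabolism covered FoxO targets, glucose uptake with glycolysis and glycogen, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation with PPAR targets, oxidative phosphorylation, mitochondrially encoded genes, insulin signalling components and glucose-responsive MondoA targets. Lists on regulation covered ribosome biogenesis, ribosomal proteins, immediate early genes, inflammation and injury, heat shock, the circadian clock, glucocorticoid response, the amino acid and ATF4 response, endoplasmic reticulum chaperones, muscle growth regulators, vascular growth and interferon response. Marker lists covered slow fibres, fast fibres, endothelium, smooth muscle and pericytes, fibroblasts and matrix, adipocytes, macrophages and monocytes, neutrophils, lymphocytes, red blood cells, satellite cells, nerve and Schwann cells, and skin keratinocytes. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with an estimated correlation, with p adjusted over the 34 lists of a comparison. Member counts are given after adjustment over all genes and after adjustment over the list alone.

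The pipeline was tested on simulated counts with 50 genes planted at each fold. In insulin against basal it recovered 42% of genes planted at a fold of 2 and 98% at a fold of 4, with 7 false calls among 184. In sample 2 against sample 0 it recovered 30% and 86%, with 9 false calls among 170. Between samples 2 and 1 it recovered 48% and 82%, with 5 false calls among 172. Simulated counts were drawn independently for each library given its dog, with no response that differed between dogs. Changes were planted only in genes above a minimum level, and in more genes than edgeR called in the data. These rates therefore need not hold for the data.

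The alternatives were RLE scaling in edgeR, DESeq2 1.42.0, no filter on low counts, a filter asking for 1 CPM in 3 libraries, a model with no dog block, voom with the dog as a random block, and voom with the dog fixed and a correlation within dog and stimulation. Further ones were insulin libraries summed per dog, the mean of samples 1 to 3 against sample 0, fits on only the libraries of the compared groups, and leaving out each dog and each library in turn. Leaving out dog 1 sample 2 together with dog 2 sample 0 was added after the data were seen. Counting error alone allows up to 3 counts for a gene with 0 counts, or between 0.0366 and 0.0664 CPM depending on the library. Reads carried no molecular identifiers, so this limit covers counting error only. Totals exceeded the stated depth, and whether both ends of a fragment or several alignments of a read were counted apart was not given. If they were, a count is less than 1 independent observation and the limit is higher. Gene length, isoforms and variants were not analysed here.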

Results

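Gene expression was measured by RNA sequencing in biopsies of the biceps femoris, a muscle of the thigh, from 4 wild-type dogs aged 9 to 10 months. Basal libraries (sample 0) came from dogs 2, 3 and 4 (n = 3). Insulin-stimulated libraries came from dogs 1 to 4 as sample 1 (n = 4) and sample 2 (n = 4), and from dogs 1 and 2 as sample 3 (n = 2). Raw counts were used throughout. Totals ranged from 45200416 to 81948641 counts per library, all above the approximate depth in the labels, for a reason that the labels do not give. In dog 1 samples 1, 2 and 3 held 64533417, 81948641 and 60525614 counts. In dog 2 samples 0, 1, 2 and 3 held 68278235, 72052490, 59980330 and 58023406 counts. In dog 3 samples 0, 1 and 2 held 57605455, 54624433 and 51109721 counts, and in dog 4 they held 45200416, 47333352 and 60287430 counts. ACTA1, the skeletal muscle actin, took from 10.4% to 13.7% of the counts in 12 libraries and 18.4% in dog 1 sample 2, which also had the lowest mean correlation with the other libraries (r = 0.943).

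**Figure D1:**
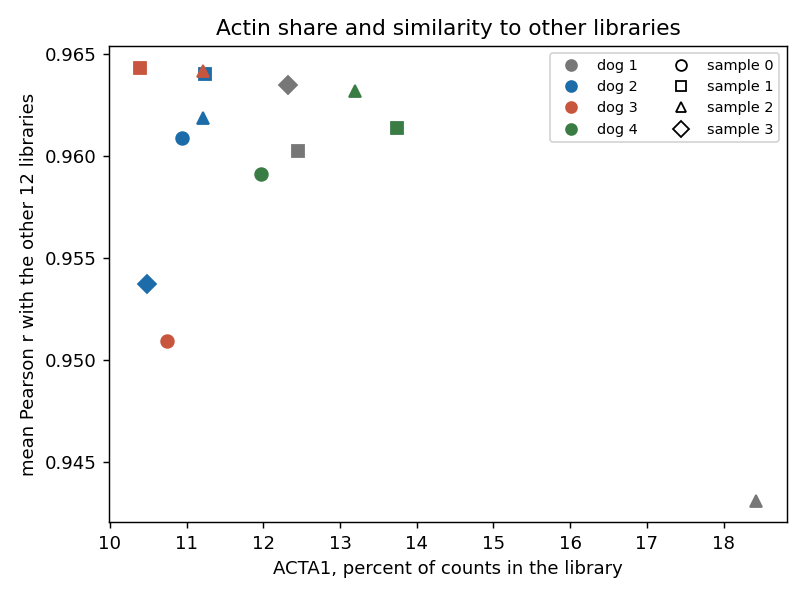
Each point is 1 library, with the share of counts from ACTA1 (percent) on the horizontal axis and the mean Pearson r of log2 CPM with the other 12 libraries on the vertical axis. Dog 1 sample 2 lies apart at 18.4% and r = 0.943.

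The comparison of insulin with basal libraries asked which muscle transcripts differ with the stimulation named in the labels. PDK4 (ENSCAFG00000002129), the kinase that switches off pyruvate dehydrogenase, fell from 1759 ± 723 CPM (SD, n = 3) to 143 ± 128 CPM (n = 10), a log2 fold change of -3.55 ± 0.37 (SE; adjusted p = 0.00187). TRIM63 (ENSCAFG00000012671), a muscle ubiquitin ligase active in wasting, fell from 183 ± 47.9 to 36.1 ± 13.4 CPM (log2 fold change -2.22 ± 0.26, adjusted p = 0.00238). TXNIP (ENSCAFG00000011405), which restrains glucose uptake, fell from 453 ± 81.4 to 126 ± 40.7 CPM (-1.73 ± 0.28, adjusted p = 0.0301). ANGPTL4 (ENSCAFG00000018506), an inhibitor of lipoprotein lipase, fell from 35.1 ± 26.0 to 4.88 ± 2.67 CPM (-2.74 ± 0.41, adjusted p = 0.0217). MYOD1 (ENSCAFG00000009066), a transcription factor of the muscle lineage, rose from 1.83 ± 0.999 to 10.2 ± 4.36 CPM (2.76 ± 0.36, adjusted p = 0.00561).

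The other named genes that fell were the nuclear receptor NR4A2 (ENSCAFG00000009209; -3.19 ± 0.43, from 6.36 to 1.01 CPM), the chromatin factor ARID5B (ENSCAFG00000012991; -2.54 ± 0.27, from 35.9 to 7.79 CPM) and the kinase SGK1 (ENSCAFG00000000217; -1.68 ± 0.26, from 88.7 to 21.6 CPM). The kinase MAP3K13 (ENSCAFG00000013230) fell with a log2 fold change of -1.54 ± 0.26, the chaperone cofactor DNAJB4 (ENSCAFG00000020357) with -1.45 ± 0.24 and the transcriptional regulator IFRD1 (ENSCAFG00000003322) with -1.45 ± 0.22. Genes that rose were NPPC (ENSCAFG00000011135), which encodes C-type natriuretic peptide (3.02 ± 0.42, from 0.362 to 3.02 CPM), the solute carrier SLC35E4 (ENSCAFG00000012834; 1.96 ± 0.22, from 3.44 to 11.5 CPM) and MID1IP1 (ENSCAFG00000014056), a partner of acetyl-CoA carboxylase (1.12 ± 0.20, from 12.5 to 28.0 CPM). Adjusted p for these 9 genes lay between 0.00187 for ARID5B and 0.0478 for MID1IP1. ZFAND5 (-1.20), HBP1 (-0.84), GTF2B (-0.85), DUSP10 (-0.96), BDNF (-2.22) and the unnamed gene ENSCAFG00000029110 (-3.39) also passed, and are named here after their values were seen. With 1 of the 13 libraries left out in turn, ZFAND5 stayed past the threshold in 11 fits, ENSCAFG00000029110 in 4, HBP1, BDNF and DUSP10 in 3 and GTF2B in 1. Their highest adjusted p was 0.0556 for ZFAND5 and 0.382 for DUSP10 without dog 2 sample 0, and 0.332 for HBP1, 0.387 for BDNF and 0.472 for GTF2B and ENSCAFG00000029110 without dog 4 sample 0.

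In all, edgeR called 20 of 14629 genes, 4 higher and 16 lower with insulin, each in the same direction in 3 of 3 dogs, and 603 genes had an unadjusted p under 0.05. That is less than the share of 0.05 of the 14629 genes that chance alone would give. The corresponding counts given below for the other comparisons are also under that share. The balance of directions depended on dog 2 sample 0, and also on the method. Without that library 22 genes passed, 14 higher and 8 lower, and only 9 of the 20 were among them, although all 20 kept their direction. Without the whole of dog 2, 25 genes passed, 15 higher and 10 lower, 7 of the 20 among them. Without dog 1, 20 genes passed, 16 of the called 20 among them. Without dog 3, 6 genes passed, 0 higher and 6 lower, all among the 20. Without dog 4, 4 genes passed, which were PDK4, NPPC and ARID5B of the 20, and IER5. TRIM63 and SLC35E4 therefore did not pass without dog 4. PDK4, TRIM63, SLC35E4 and ARID5B stayed past the threshold when any 1 of the 13 libraries was left out, while MYOD1, NPPC and NR4A2 did in 11 of these 13 fits, ANGPTL4 in 7, SGK1, IFRD1 and DNAJB4 in 6, MAP3K13 in 4, TXNIP in 3 and MID1IP1 in 2. The highest adjusted p was 0.284 for TXNIP, 0.277 for ANGPTL4, 0.281 for SGK1, 0.103 for NR4A2 and 0.472 for MID1IP1 without dog 4 sample 0, 0.0583 for MYOD1, 0.0751 for NPPC and 0.358 for MAP3K13 without dog 3 sample 0, and 0.240 for IFRD1 and 0.332 for DNAJB4 without dog 2 sample 0. The count fell to 8 without dog 3 sample 0 and to 7 without dog 4 sample 0. It was 13 without dog 2 sample 1, 10 without dog 2 sample 2, 10 without dog 2 sample 3, 9 without dog 3 sample 1, 11 without dog 3 sample 2, 9 without dog 4 sample 1 and 8 without dog 4 sample 2. With insulin libraries summed per dog, so that each dog counts once, only TRIM63 passed (-2.20, adjusted p = 0.0132), with PDK4 at an adjusted p of 0.379. DESeq2 called 104 genes, 46 higher and 58 lower, and a fit with no dog block called 6.

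**Figure D2:**
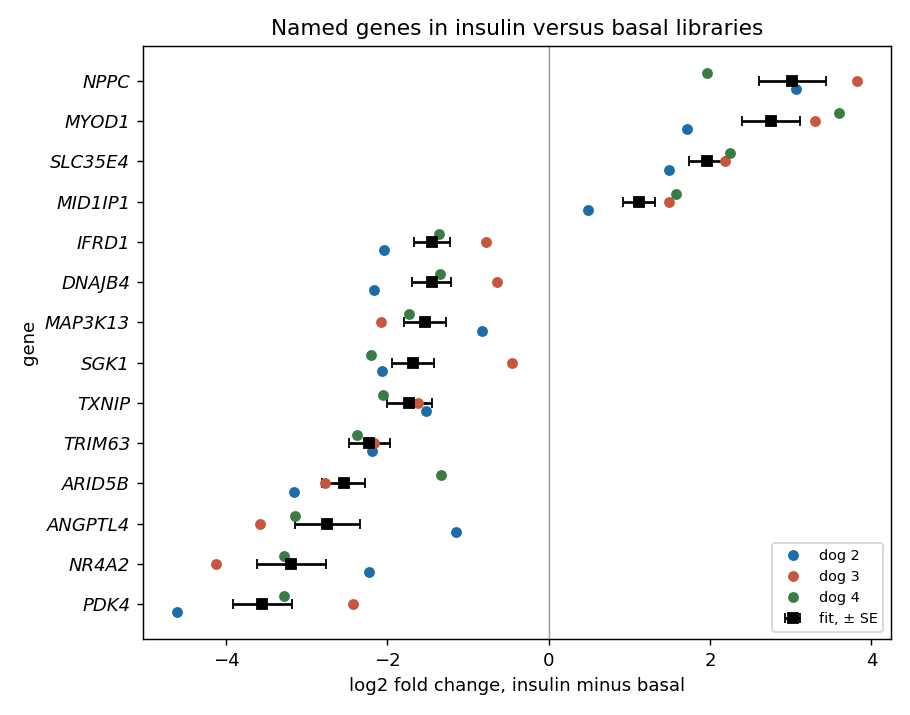
Black squares with bars give the fitted log2 fold change of insulin minus basal ± SE for the 14 genes named by the rule, and coloured points give the change within dogs 2, 3 and 4. All 14 genes lie on 1 side of 0 in each dog, from -3.55 for PDK4 to 3.02 for NPPC.

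**Figure D3:**
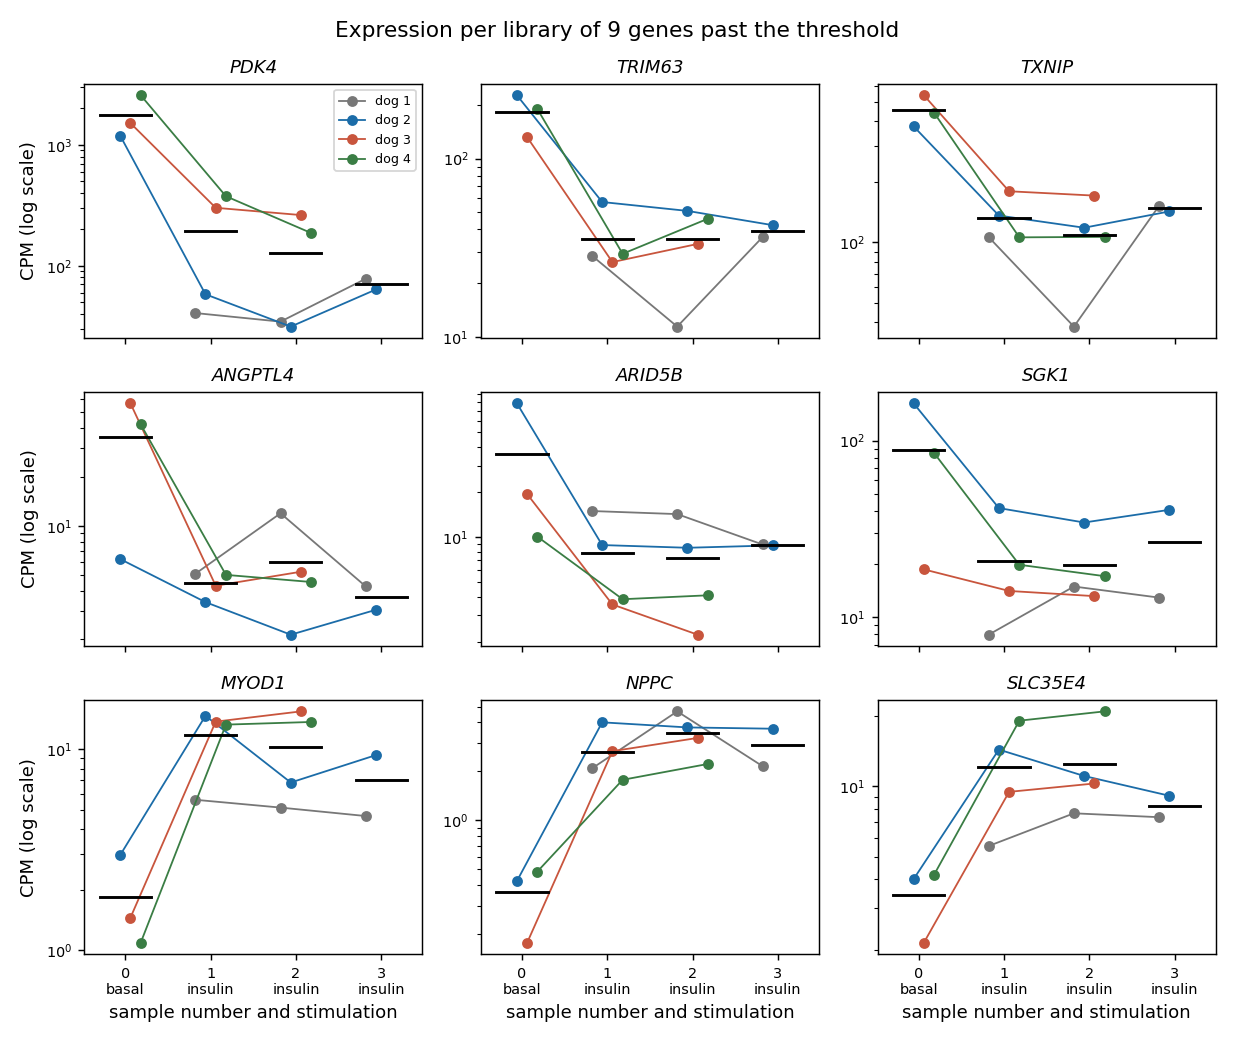
CPM on a log scale for 9 genes past the threshold, by sample number and stimulation, with lines joining the libraries of a dog and bars at the group means. PDK4 had a basal mean of 1759 CPM and an insulin mean of 143 CPM, and MYOD1 had 1.83 and 10.2 CPM.

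FoxO target genes, which are active when insulin signalling is low, fell as a group. Of 24 members measured, 0 were higher and 2 lower after adjustment over all genes (PDK4 and TRIM63), and 1 was higher and 6 lower when adjusted over the list alone. The median log2 fold change was -0.45 (camera adjusted p = 9.75e-13, and adjusted p = 0.0313 with an estimated correlation). KLF15 had a log2 fold change of -1.04 ± 0.19 (adjusted p = 0.0586), FBXO32, another muscle ubiquitin ligase, had -1.35 ± 0.56 (adjusted p = 1) and GADD45A had 1.15 ± 0.30 (adjusted p = 0.319), so none of these passed over all genes. KLF15 passed without dog 1 sample 2 (adjusted p = 0.0335) and GADD45A without dog 2 sample 2 (adjusted p = 0.0161). FOXO1 had 0.41 ± 0.28 (adjusted p = 1). Neutrophil markers had a median of -1.44 and red blood cell markers a median of -1.20 between the same libraries.

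Glucocorticoid response genes fell as a group, with a median of -0.36 (camera adjusted p = 2.66e-08, and adjusted p = 0.00675 with an estimated correlation). KLF15, SESN1 and FOXO3 were named both in this list and among FoxO targets. Of 16 members, 0 were higher and 2 lower over all genes (SGK1 and ANGPTL4), and 0 were higher and 5 lower when adjusted over the list alone. ERRFI1 had a log2 fold change of -0.87 ± 0.20 (adjusted p = 0.165). Immediate early genes, which respond within minutes to many stimuli, had a median of -0.76 (camera adjusted p = 4.18e-08), and the call was lost with adjusted p = 0.192 with an estimated correlation. Of 28 members, 0 were higher and 1 lower over all genes (NR4A2), and 2 were higher and 11 lower when adjusted over the list alone. IER5 had -2.62 ± 0.55 (adjusted p = 0.110), BTG2 had -1.71 ± 0.44 (adjusted p = 0.308) and KLF10 had 0.99 ± 0.26 (adjusted p = 0.319). Without dog 2 sample 0 the median of the immediate early list was 0.04 (adjusted p = 0.169), and without dog 4 sample 0 IER5 passed (adjusted p = 0.0157). The neutrophil list (median -1.44) and the red blood cell list (median -1.20) moved in the same direction between these libraries.

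**Figure D4:**
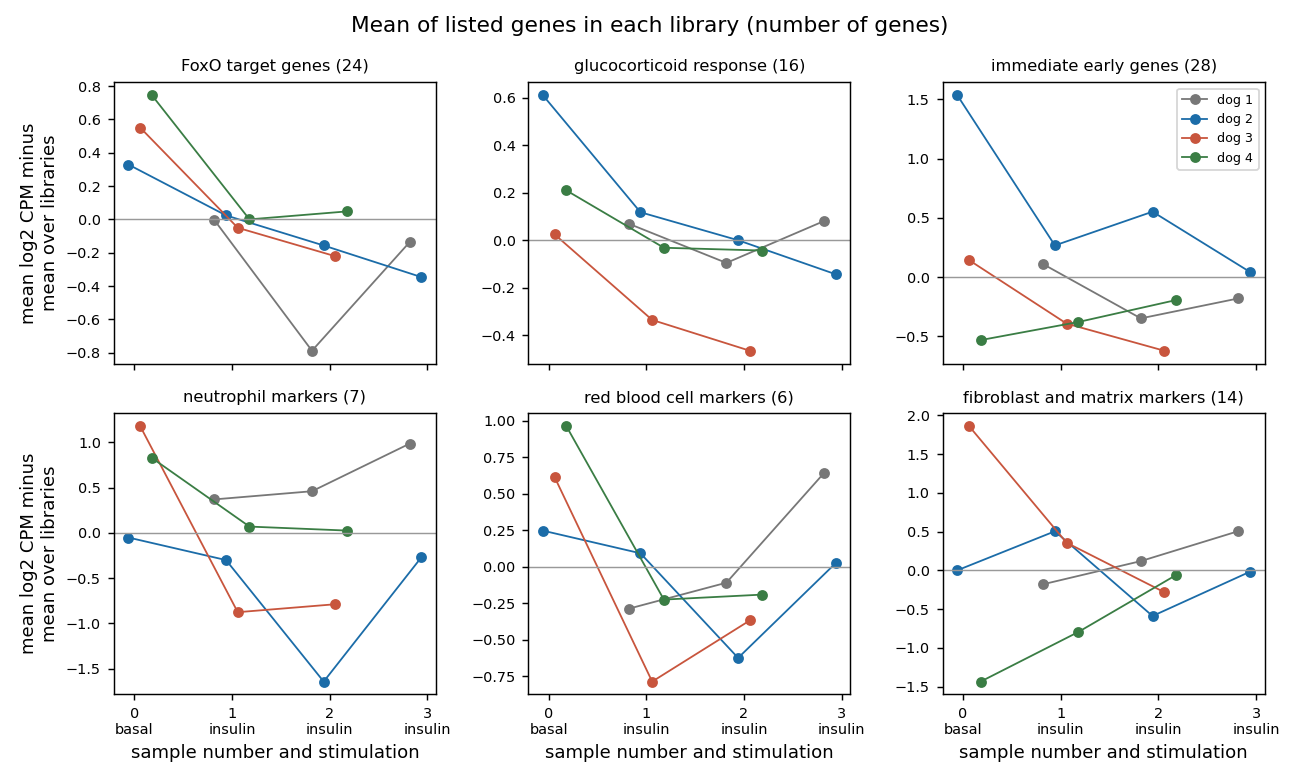
Mean log2 CPM of the measured members of 6 lists in each library, minus the mean over libraries, by sample number and stimulation, with lines joining the libraries of a dog. The basal library of dog 2 is the highest of the immediate early list, and that of dog 3 is the highest of the fibroblast list.

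Fatty acid oxidation and PPAR target genes had PDK4 and ANGPTL4 lower and 0 higher among 25 members over all genes, and 1 higher and 4 lower when adjusted over the list alone. Their median was 0.04, their mean was -0.27 and the test pointed down (camera adjusted p = 0.0583, and adjusted p = 0.448 with an estimated correlation). CPT1A, which admits fatty acids to mitochondria, had a log2 fold change of -1.35 ± 0.28 (adjusted p = 0.110), UCP3 had 386 ± 96.1 CPM in basal and 170 ± 42.9 CPM in insulin libraries (adjusted p = 0.154) and PPARGC1A had 0.67 ± 0.21 (adjusted p = 0.650). In the list for glucose uptake, glycolysis and glycogen, 0 of 21 members passed over all genes, and 2 were higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.0868). These were PPP1R3C, a glycogen-targeting phosphatase subunit, at 2.06 ± 0.40 (from 85.2 to 332 CPM, adjusted p = 0.0993), and the glucose transporter SLC2A1 at 0.95 ± 0.26 (adjusted p = 0.344). HK2 had 0.04 ± 0.38 and SLC2A4, the insulin-regulated glucose transporter, had -0.02 ± 0.18 (adjusted p = 1 for both). Among 8 glucose-responsive MondoA targets TXNIP was lower and 0 were higher over all genes, and 2 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.774). ARRDC4, a relative of TXNIP, had 0.79 ± 0.18 (adjusted p = 0.198). The fatty acid oxidation list passed downward without dog 2 sample 0 (adjusted p = 0.00220), dog 3 sample 0 (0.0374), dog 4 sample 1 (0.0350), dog 1 sample 3 (0.0496) or dog 2 sample 3 (0.0384). The glycolysis and glycogen list passed upward without dog 2 sample 0 (0.000881) or dog 2 sample 3 (0.0384), PPP1R3C passed without dog 2 sample 0 (0.000317) and UCP3 without dog 1 sample 2 (0.0206). Neutrophil and red blood cell markers (medians -1.44 and -1.20) were lower between the same libraries.

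Among 18 muscle growth regulators MYOD1 was higher and 0 were lower over all genes, and 2 were higher and 0 lower when adjusted over the list alone, the second being MYOG at 1.37 ± 0.31 (adjusted p = 0.188). The median of this list was -0.01 while its mean was 0.13 and its test pointed up (camera adjusted p = 0.164). Without dog 2 sample 0 this list and MYOG passed upward (adjusted p = 4.77e-05 and 0.00573), and without dog 1 sample 2 the clock list passed downward (adjusted p = 0.0377). The circadian clock list had 0 of 18 members past the threshold over all genes, and 3 higher and 5 lower when adjusted over the list alone (median -0.30, camera adjusted p = 0.122). ARNTL and BHLHE40 had 1.38 ± 0.36 and 0.94 ± 0.23 (adjusted p = 0.302 and 0.263), and CRY2 and DBP had -0.60 ± 0.16 and -0.77 ± 0.21 (adjusted p = 0.385 and 0.388). Vascular growth genes had a median of 0.15 (camera adjusted p = 0.0148), with 0 of 19 members past the threshold over all genes and 0 when adjusted over the list alone, and adjusted p = 0.448 with an estimated correlation. VEGFA had 1.05 ± 0.39 (adjusted p = 0.915) and ANGPT2 had 0.92 ± 0.30 (adjusted p = 0.681). The vascular list was not past the threshold without dog 2 sample 0 (adjusted p = 0.123), dog 4 sample 0 (0.126), dog 2 sample 1 (0.0810) or dog 4 sample 2 (0.108). Neutrophil and red blood cell markers (medians -1.44 and -1.20) were lower between the same libraries.

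Neutrophil markers fell as a group (median -1.44, camera adjusted p = 2.66e-08), and the call was lost with adjusted p = 0.110 with an estimated correlation. Of 7 members, 0 passed over all genes, and 0 were higher and 5 lower when adjusted over the list alone, among them CSF3R at -1.46 ± 0.51 and S100A12 at -1.05 ± 0.35 (adjusted p = 0.808 and 0.724 over all genes). Red blood cell markers had a median of -1.20 (camera adjusted p = 0.00740), with adjusted p = 0.139 with an estimated correlation and adjusted p = 0.0530 without dog 4 sample 0. Of 6 members, 0 passed over all genes, and 0 were higher and 1 lower when adjusted over the list alone (ALAS2 at -1.89 ± 0.54, adjusted p = 0.430 over all genes). Most members were scarce, with basal means of 2.08 CPM for CSF3R and 1.87 CPM for ALAS2, and in insulin libraries only 2 of the 7 neutrophil and 2 of the 6 red blood cell markers had a mean of 1 CPM or more. The more abundant members moved little or the other way. S100A8 had 42.9 CPM in basal and 31.0 CPM in insulin libraries (log2 fold change -0.50 ± 0.37), GYPC had 26.4 and 30.5 CPM (0.10 ± 0.15) and SLC25A37 had a log2 fold change of 0.19 ± 0.18 (adjusted p = 1 for all 3).

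Fibre type and energy lists had 0 members past the threshold over all genes. Slow fibre markers had a median of 0.09 (camera adjusted p = 0.560) with 0 higher and 1 lower when adjusted over the list alone, LMOD2 at -1.01 ± 0.27 (adjusted p = 0.319 over all genes). Fast fibre markers had a median of 0.05, a mean of -0.01 and a test that pointed down (camera adjusted p = 0.761). Oxidative phosphorylation genes had a median of 0.10 (camera adjusted p = 0.0583), mitochondrially encoded genes -0.04 (0.919), ribosomal proteins -0.08 (0.0868) and ribosome biogenesis genes 0.03 (0.228). Fatty acid synthesis genes had a median of 0.20 (camera adjusted p = 0.0966), with the regulator SREBF1 at 0.49 ± 0.32 (adjusted p = 1), and cholesterol synthesis genes had 0.06 (0.526). Insulin signalling components had a median of -0.10 (camera adjusted p = 0.0932), with INSR at -0.07 ± 0.29 and the scarce IRS2 at -1.84 ± 0.80 (adjusted p = 1 for both). Without dog 4 sample 0 mitochondrially encoded genes turned upward past the threshold (median 0.40). Slow fibre markers (0.40) and oxidative phosphorylation genes (0.17), which already pointed up, also passed in that fit. Oxidative phosphorylation genes passed upward too without dog 2 sample 1 (0.13), dog 1 sample 2 (0.10) or dog 4 sample 2 (0.11). Without dog 3 sample 0 mitochondrially encoded genes (-0.47), ribosomal proteins (-0.21) and insulin signalling components (-0.17) passed downward and fatty acid synthesis genes (0.71) upward, and fatty acid synthesis (0.43) and ribosomal proteins (-0.16) also did without dog 3 sample 2, and ribosomal proteins without dog 2 sample 3 (-0.14). In these lists other than slow fibres, 0 members passed when adjusted over the list alone.

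Among stress lists, the heat shock response had DNAJB4 lower and 0 higher both over all genes and adjusted over the list alone, a median of 0.00, a mean of -0.10 and a test that pointed down (camera adjusted p = 0.230). Inflammation and injury genes had a median of 0.02 (camera adjusted p = 0.0932), the amino acid and ATF4 response 0.10 (0.164), endoplasmic reticulum chaperones -0.10 (0.164) and interferon response genes 0.01 (0.603). Among markers of other cells, medians were 0.07 for endothelium (camera adjusted p = 0.496), 0.21 for smooth muscle and pericytes (0.0556), -0.34 for fibroblasts and matrix (0.0868) and 0.14 for adipocytes (0.222). Satellite cells had a median of 0.11 (0.300) and nerve and Schwann cells 0.40 (0.268). Macrophages and monocytes had a median of -0.24 and a mean of 0.12, and lymphocytes a median of 0.17 and a mean of -0.06, and both tests pointed down (0.648 and 0.409). Skin keratinocyte markers had a median of -0.39 (0.0868), with 0 higher and 1 lower when adjusted over the list alone, TP63 at -0.45 ± 0.15 (adjusted p = 0.717 over all genes). In the other lists of this paragraph, 0 members passed over all genes or when adjusted over the list alone.

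Several marker and stress lists depended on 1 library in insulin against basal. Without dog 3 sample 0 the fibroblast (median 0.54), macrophage (0.50), endothelial (0.40), smooth muscle (0.72), adipocyte (0.85), nerve and Schwann cell (1.80), interferon (0.52) and inflammation (0.37) lists passed upward and the heat shock list (-0.13) downward. Without dog 4 sample 0 the fibroblast (-0.82) and macrophage (-0.77) lists passed downward. Without dog 2 sample 0 the fibroblast list (-0.62) passed downward, and the inflammation (0.34) and ATF4 (0.14) lists passed upward. Fibroblast markers also passed downward without dog 2 sample 1 (-0.42), dog 4 sample 2 (-0.48) or dog 2 sample 3 (-0.37), nerve and Schwann cell markers upward without dog 3 sample 2 (1.15) and inflammation genes upward without dog 2 sample 3 (0.13). Smooth muscle markers passed upward without dog 1 sample 1 (0.21), dog 4 sample 1 (0.22), dog 2 sample 2 (0.27), dog 3 sample 2 (0.46), dog 1 sample 3 (0.21) or dog 2 sample 3 (0.23).

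Sample 2 was then compared with sample 0, in a model of all 13 libraries in which dogs 2, 3 and 4 had both. PDK4 fell by 3.97 ± 0.44 on the log2 scale (adjusted p = 0.0344), to 129 ± 115 CPM (SD, n = 4) in sample 2. ARID5B fell by 2.54 ± 0.33, TRIM63 by 2.28 ± 0.32, and TXNIP by 1.99 ± 0.28, and LMOD2, an actin filament nucleator of muscle, was 2.83-fold lower (SE 0.21 on the log2 scale). NPPC rose by 3.27 ± 0.45 and SLC35E4 by 2.02 ± 0.25. These 7 genes, 2 higher and 5 lower, were all that edgeR called (adjusted p up to 0.0474, 724 genes at an unadjusted p under 0.05), each in the same direction in 3 of 3 dogs, and DESeq2 called 73. Without dog 2 sample 0 the balance turned, with 12 genes past the threshold, 9 higher and 3 lower, and 2 of the 7 among them.

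The count of 7 in sample 2 against sample 0 rested on single libraries. It was 0 without dog 1 sample 1, dog 1 sample 3, dog 2 sample 1, dog 2 sample 3, dog 3 sample 1, dog 4 sample 1 or dog 4 sample 2. It was 1 without dog 2 sample 2 or dog 3 sample 2, 2 without dog 3 sample 0, 3 without dog 4 sample 0, 11 without dog 1 sample 2 and 12 without dog 2 sample 0. Among lists at the preset correlation, FoxO targets (median -0.59, camera adjusted p = 9.34e-11), glucocorticoid response (-0.48, 5.14e-05), immediate early genes (-0.58, 0.000236) and insulin signalling components (-0.20, 0.0409) were lower, as were neutrophil (-1.60, 1.31e-07) and red blood cell markers (-1.25, 0.0106). With an estimated correlation none of the 34 lists passed, and the lowest adjusted p = 0.0730 with an estimated correlation belonged to FoxO targets and glucocorticoid response. Of 24 FoxO targets 0 were higher and 2 lower over all genes (PDK4 and TRIM63), and 0 were higher and 6 lower when adjusted over the list alone. Oxidative phosphorylation genes were higher at the preset correlation only (0.24, 1.66e-05, and adjusted p = 0.723 with an estimated correlation), and dog 1 sample 2 stood apart in that list, at 0.60 above its mean over libraries against 0.0063 to 0.043 in the other 3 libraries of sample 2.

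Sample 1 against sample 0 gave 0 genes past the threshold with edgeR, with 438 at an unadjusted p under 0.05 and 40 called by DESeq2. Among genes with a symbol and a mean log2 CPM of at least 1, the 5 of lowest p, none significant, were PDK4 (-3.41 ± 0.42, adjusted p = 0.0546), SLC35E4 (1.94 ± 0.25, 0.0546), MYOD1 (2.91 ± 0.40, 0.0553), ARID5B (-2.39 ± 0.33, 0.0553) and NPPC (2.85 ± 0.44, 0.0851), each in 1 direction in 3 of 3 dogs. The count was 8 without dog 2 sample 0, 4 without dog 1 sample 2, 2 without dog 3 sample 0, 1 without dog 4 sample 0 and 1 without dog 2 sample 2. At the preset correlation FoxO targets (median -0.36), glucocorticoid response (-0.19), immediate early genes (-0.72), ribosomal proteins (-0.21), neutrophil markers (-1.30) and red blood cell markers (-1.27) were lower. With an estimated correlation none of the 34 lists passed, and glucocorticoid response had the lowest value (adjusted p = 0.0947 with an estimated correlation, 0.129 for FoxO targets and 0.583 for ribosomal proteins). Vascular growth genes (0.44), smooth muscle markers (0.54) and inflammation genes (0.23) were higher at the preset correlation only, and glycolysis and glycogen genes passed upward with a median of -0.05 and a mean of 0.28. These 4 calls were lost with adjusted p = 0.318 with an estimated correlation for vascular growth, smooth muscle and glycolysis and 0.582 for inflammation. Of 24 FoxO targets 0 passed over all genes, and 1 was higher and 5 lower when adjusted over the list alone.

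Sample 3 against sample 0 rested on 2 insulin libraries, of which only that of dog 2 had a basal partner. EdgeR called 0 genes, with 547 at an unadjusted p under 0.05, and DESeq2 called 24. The lowest adjusted p over all genes was 0.198. With a symbol and a mean log2 CPM of at least 1 required, the 5 genes of lowest p, none significant, were ARID5B (-2.93 ± 0.44, adjusted p = 0.249), SLC35E4 (1.76 ± 0.31), ZFAND5 (-1.37 ± 0.24), PDK4 (-3.11 ± 0.58) and NPPC (2.76 ± 0.52), the last 4 at an adjusted p of 0.458, each in that direction in 1 of 1 dog. The count was 2 without dog 2 sample 0, 1 without dog 1 sample 2 and 1 without dog 4 sample 0. At the preset correlation 3 lists were higher (ribosomal proteins, slow fibres, adipocytes) and 6 lower (FoxO targets, immediate early genes, heat shock, glucocorticoid response, insulin signalling components, fast fibres). Neutrophil and red blood cell markers did not pass here (medians -0.85 and -0.18, camera adjusted p = 0.282 and 0.717), and with an estimated correlation none of the 34 lists passed (lowest adjusted p = 0.0657 with an estimated correlation, glucocorticoid response).

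Samples 2 and 1, both from insulin-stimulated muscle of 4 dogs, were compared to ask whether libraries under 1 stimulation label differed by sample number. EdgeR called 0 genes, with 495 at an unadjusted p under 0.05, and DESeq2 called 0. The 5 genes of lowest p with a symbol and a mean log2 CPM of at least 1, none significant, were LMOD2 (-0.81 ± 0.19), NCAPH2 (0.57 ± 0.14), GCAT (0.65 ± 0.17), SERF2 (0.57 ± 0.16) and NCEH1 (-0.91 ± 0.26), each at an adjusted p of 0.902 and in 1 direction in 4 of 4 dogs. Slow fibre markers had 0 members higher and 2 lower when adjusted over the list alone. Oxidative phosphorylation (median 0.29), ribosomal protein (0.09) and heat shock (0.12) lists were higher at the preset correlation, and each call was lost (adjusted p = 0.924 with an estimated correlation). Dog 1 sample 2 stood apart in the oxidative phosphorylation list (0.60 above its mean over libraries, 0.0063 to 0.043 in the other 3 libraries of sample 2) and had the lowest share of mitochondrial transcripts (0.285% of counts). Mitochondrially encoded genes (-0.64), smooth muscle markers (-0.48), nerve and Schwann cell markers (-0.57), endothelium (-0.29), vascular growth (-0.25), FoxO targets (-0.22), slow fibres (-0.18) and insulin signalling components (-0.11) were lower at the preset correlation. These 8 calls were also lost, each at adjusted p = 0.924 with an estimated correlation. A joint edgeR test of any difference among samples 1, 2 and 3 called 0 genes, with 476 at an unadjusted p under 0.05 and 2 called by DESeq2 (FHL2 and SIX2), and its 5 genes of lowest p under the same 2 conditions were FHL2, PLCD4, AADAC, GCAT and MED16 (adjusted p = 0.931).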

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

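The tests of steady drift, of the muscle share, of blood in the biopsies, of a library from another dog and of regrouped libraries in insulin against basal were chosen after the result was seen. Over the 2 groups of 4 libraries (samples 1 and 2), 382 values in all were examined for a library far from the other 3, and 18 were found in all. Chance gives about 1 in 20, and the number found is near that share. Values of a library are not independent, so this does not show that each value found is due to chance. In sample 2, all values found except those of CDH19 and CKM belonged to dog 1, whose sample 2 is the third pattern below. In sample 1, dog 1 had 5.60 CPM of MYOD1 (13.3 to 14.7 in the others), 0.424 CPM of CNN1 (1.62 to 1.75), 10.6 CPM of MRC1 (2.46 to 2.95) and a MondoA target mean of -0.45 on the log2 scale (0.19 to 0.27). TRIM63 was at 57.0 CPM in dog 2 sample 1 (26.2 to 29.2 in the others). Dog 4 sample 1 had 17.3 CPM of DSP (3.39 to 4.40) and 12761 genes with 10 or more counts (13550 to 13677). In sample 2, dog 1 had 32.4 CPM of MID1IP1 (27.4 to 28.2), 4.92 of SLC2A1 (3.27 to 3.49), 859 of UQCRB (462 to 478), 732 of NDUFA10 (451 to 484) and 378 of HERPUD1 (171 to 182). It had 32.0 CPM of VEGFA (150 to 167), 2.75 of SDC4 (24.7 to 35.4), an oxidative phosphorylation mean of 0.60 (0.0063 to 0.043) and a mean correlation of 0.943 with the other libraries (0.962 to 0.964). Dog 2 sample 2 had 0 CPM of CDH19 (0.264 to 0.372), with a limit of 0.05 CPM at this depth, and 5.37% of its counts from CKM (9.41% to 10.2%).

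The first pattern was the 20 genes called in insulin against basal. Regrouping the libraries argues against chance for this count but cannot exclude it, since only dogs 2 to 4 held both kinds of library. Taking 1 library of each of dogs 2 to 4 as basal gave as many genes in 1 of 36 groupings (20 genes, highest other 14), and taking any 3 libraries gave as many in 1 of 99 groupings (highest other among these 7). The 99 came from 100 drawn at random from the larger number possible, of which 1 could not be fitted, and the grouping with 14 genes was not among them. With the neutrophil mean as a covariate, the median log2 fold change of the 16 genes called lower was -1.97 against -1.70 without it. All 20 genes kept their sign but 0 passed with the covariate, and the median SE rose from 0.26 to 0.42. The covariate correlates with stimulation (r = -0.743 with the dog removed), so it cannot decide whether blood cells were the cause. PDK4 fell by 1616 CPM where S100A8, the most abundant neutrophil marker given here, was only 11.9 CPM higher in basal libraries. These levels argue against neutrophils as the source for PDK4 but do not cover scarce called genes such as NR4A2. A steady drift with sample number is argued against by a median signed change of 0.0757 between samples 1 and 2 (quartiles -0.033 and 0.18) against 1.83 between samples 0 and 1. Calling these genes favoured a small spread among insulin libraries, so the 50 genes of lowest p in sample 2 against sample 0 were also taken. Both steps enter that choice with equal weight. The error of sample 0, which had fewer libraries than sample 2, enters only the first step, so the choice may still favour that step. The medians of the 50 genes were 1.19 for the first step (quartiles 0.83 and 2.19) and 0.27 for the second (quartiles 0.081 and 0.39), and the second was as large as the first in 4 of the 50. Any difference that sets sample 0 apart from the other sample numbers stays open beside insulin, since every basal library is sample 0.

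The second pattern was the lower neutrophil and red blood cell markers with insulin, in lists of 7 and 6 measured genes of which 0 belonged to another list. A lower share of muscle in the basal biopsies is argued against by lists of other cells over the dogs together, but not in dog 3. The 8 lists first used held satellite cells, which belong to muscle, and lacked keratinocytes, and their 87 members had a median log2 fold change of 0.0275 (quartiles -0.29 and 0.35). With keratinocytes in place of satellite cells, 83 members had a median of -0.0112 (quartiles -0.31 and 0.29), although the keratinocyte list alone had -0.39. These medians join dogs that differed. Relative to all libraries, the fibroblast mean in dog 3 was 1.86 in the basal library and 0.36 and -0.28 in the insulin libraries. In dog 4 it was -1.43 in the basal library and -0.79 and -0.061 in the insulin libraries. The basal library of dog 2 lay within the range of its insulin libraries. A lower share of muscle stays open for dog 3. Blood in the basal biopsies cannot be told apart from other sources, because the only test run on it used the lists that make the pattern. Both lists were higher in the basal library in 3 of 3 dogs, by 0.69, 2.01 and 0.78 for neutrophils and by 0.42, 1.19 and 1.17 for red blood cells on the log2 scale in dogs 2, 3 and 4. S100A8 had 42.9 CPM in basal and 31.0 CPM in insulin libraries, while GYPC had 26.4 and 30.5 CPM. A response of circulating cells to insulin was not tested and stays open.

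The third pattern was dog 1 sample 2, which stood apart from the other 12 libraries. It had 238 genes over 4-fold away from the mean of the other libraries of its dog after TMM scaling, where the highest other library had 86, which argues against a few abundant genes as the cause. With every library thinned to the lowest total its mean correlation was 0.941 and the lowest other was 0.950, which argues against depth. Of 9 genes that set dog 1 samples 1 and 3 apart from all other dogs, 88.9% were on the side of dog 1 (exact 95% interval 51.8% to 99.7%). This argues against a library of dogs 2, 3 or 4. The interval takes the 9 genes as independent, which they need not be. The genes were chosen against these dogs only, so they cannot exclude a dog outside the series. No biological explanation was tested.

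Other groupings of the libraries were also run for the comparisons between sample numbers. Chance cannot be excluded for sample 2 against sample 0, where 2 of 35 groupings gave as many genes (7 genes, highest other 163). The other grouping joined dog 1 sample 2, dog 3 sample 0 and dog 4 sample 2, and why it gave so many genes was not tested. Among the 8 groupings that part 3 pairs of a dog, as the real one does, the others gave 0 genes. For sample 1 against sample 0 all 35 of 35 groupings gave at least the 0 genes found (highest other 0), and for sample 2 against sample 1 all 35 of 35 did (highest other 3). A count of 0 is reached by any grouping, so these 2 tests decide nothing.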

How the results depend on the processing

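Leaving out dog 1 sample 2 and dog 2 sample 0 together was chosen after the data were seen. Every gene called in insulin against basal kept its direction in each of 27 alternatives that tested it, the stricter filter testing 19 of the 20. The FoxO and glucocorticoid lists stayed past the threshold in 28 of 28, while the immediate early list did in 24, the neutrophil list in 27, the red blood cell list in 24 and the vascular list in 18. The 27 alternatives all used the preset correlation, and only the remaining setting used an estimated one. In that setting only the FoxO and glucocorticoid lists kept their call. The fold change of PDK4 ranged from -3.97 to -2.82 and passed in 25 of 27, the exceptions being no dog block (adjusted p = 0.0589) and insulin libraries summed per dog (0.379). TRIM63 ranged from -2.37 to -2.14 and passed in 25 of 27. TXNIP ranged from -1.88 to -1.56 and passed in 12, and MYOD1 ranged from 2.43 to 3.47 and passed in 20. The causes of the changes below were not tested, except that summing libraries and leaving out libraries leave fewer of them.

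In insulin against basal the count of 20 became 104 with DESeq2, 140 with no filter, 39 by voom with the dog fixed and a correlation within dog and stimulation, and 47 without the pair of libraries, and these fits kept 20, 20, 20 and 15 of the called genes. Without the pair 27 genes were higher and 20 lower, against 4 and 16. The fit with no filter gave every gene 1 common spread (prior degrees of freedom infinite, against 5.09 to 5.78), so its 140 calls are no fair count. The voom fit with the dog fixed estimated a correlation of -0.205 within dog and stimulation. A negative value does not make repeated insulin libraries of a dog count for less, so its 39 calls are no stricter count. The count of 20 became 6 with no dog block, 1 with insulin libraries summed per dog and 9 for the mean of samples 1 to 3. In sample 1 against sample 0 the count of 0 became 4 with RLE, 40 with DESeq2, 16 with no filter, 6 on only the compared libraries and 15 without the pair. In sample 2 against sample 0 the count of 7 became 73 with DESeq2, 28 with no filter, 0 with no dog block, 1 by voom with the dog random, 4 on only the compared libraries and 25 without the pair (15 higher and 10 lower, against 2 and 5). In sample 3 against sample 0 the count of 0 became 24 with DESeq2, 7 with no filter and 3 without the pair. In the joint test of samples 1 to 3 it became 2 with DESeq2.

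Leaving out 1 library or 1 dog gave counts from 4 to 28 in insulin against basal, 0 to 8 in sample 1 against sample 0, 0 to 12 in sample 2 against sample 0 and 0 to 2 in sample 3 against sample 0. It gave 0 to 0 in sample 2 against sample 1 and in the joint test. The list of mitochondrially encoded genes turned upward past the threshold without dog 4 (median 0.41) or its basal library (0.40), and ranged from -0.47 to 0.41 over the left-out libraries and dogs. Fibroblast markers did so without dog 3 (0.53) or its basal library (0.54), with a range from -0.82 to 0.54, and macrophage markers without dog 3 (0.50) or its basal library (0.50), with a range from -0.77 to 0.50. Where a fit left 1 library in a group, that library was assumed to vary like the others. The spread between libraries was on average far above counting error, but a mean over genes does not show whether depth limited the scarce genes.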

Other observations

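The test of the immediate early list without dog 2 was chosen after the result was seen, as were the genes of the next 2 paragraphs. Immediate early genes were high in the basal library of dog 2. EGR1 was at 129 CPM there and between 1.13 and 4.97 CPM in the other 12 libraries. FOS was at 239 CPM, ATF3 at 164 CPM, JUN at 231 CPM and the stretch-responsive gene ANKRD1 at 949 CPM in that library. The 3 insulin libraries of the same dog had between 43.3 and 108 CPM of FOS.

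Transcript levels of the myosin genes MYH1, MYH2, MYH4 and MYH7 differed between some of the dogs. MYH1, a fast myosin heavy chain, had between 1685 and 3603 CPM in dog 1 and between 14580 and 24480 CPM in dogs 2 to 4. MYH4, the fastest myosin, had between 119 and 156 CPM in dog 2 and between 9.66 and 57.8 CPM in the other dogs. MYH2 had between 14110 and 35080 CPM in dogs 1 and 2 and between 6782 and 11360 CPM in dogs 3 and 4. The ranges of MYH7 overlapped in dogs 1, 2 and 3 (3491 to 9424, 6007 to 14730 and 8079 to 13670 CPM). In dog 4 MYH7 lay above these ranges, between 15810 and 17080 CPM. The collagens COL1A1 and COL3A1 were highest in the basal library of dog 3, at 225 and 518 CPM. MYOG had 4.50 to 5.72 CPM in the insulin libraries of dog 2 and 3.94 CPM in its basal library, against 10.2 to 15.2 CPM in the insulin libraries of dogs 3 and 4 and 3.00 and 3.19 CPM in their basal libraries. These differences between dogs were not tested. G0S2, an inhibitor of the triglyceride lipase ATGL, had a log2 fold change of 3.57 ± 0.68 in insulin against basal, in 1 direction in 3 of 3 dogs, but did not pass the threshold (adjusted p = 0.0935). It passed in 7 of 27 alternatives of that comparison, among them DESeq2 (adjusted p = 1.19e-05) and leaving out dog 2 sample 0 (log2 fold change 5.38, adjusted p = 7.03e-06), with fold changes from 2.81 to 5.38. It also passed in 4 of 25 alternatives of sample 1 against sample 0, 5 of 25 of sample 2 against sample 0 and 3 of 24 of sample 3 against sample 0. The last 3 all left out dog 2 sample 0, so no dog held both sample numbers in them.

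One hypothesis was that a few members carry the lists that were lower with insulin. Without PDK4 and TRIM63 the other 22 FoxO targets were still lower, with a camera p of 0.0206 with an estimated correlation, which argues against these 2 genes as the only cause. Without SGK1 and ANGPTL4 the other 14 glucocorticoid response genes were still lower, with a camera p of 0.0145 with an estimated correlation, which argues against these as the only cause. Both p values are not adjusted over lists. KLF15, SESN1 and FOXO3 were named in both lists, so the 2 results are not independent. Whether dog 2 alone carries the immediate early list stays open, since the list had an unadjusted camera p of 0.0462 at the preset correlation without dog 2 while its median was 0.01. Dog 4 did not share a fall of this list, whose mean on the log2 scale, relative to all libraries, was -0.53 in its basal library and -0.38 and -0.19 in its insulin libraries. In dog 3 these means were 0.14 in the basal library and -0.39 and -0.62 in the insulin libraries.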
